A study of Mus musculus with 6 samples.

How the data were processed

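The series holds 6 one-colour arrays of biotin-labelled total RNA from isolated mouse pericytes, 3 of control cultures and 3 of cultures given PDGF-BB at 100 ng/ml, each for 5 days, per the labels' protocols. The authors deposited 1 table of log2 expression values with 21225 probe sets in rows and the 6 arrays in columns, and no scanner files were used here. The deposited log2 values were made with RMA, per the submitters' processing notes: a method that corrects the background, quantile-normalizes the probes across arrays and summarises each probe set on the log2 scale. The software, its version, the array's probe set definition and any filter are not given in the sources used here. That the scale is log2 was taken from the method and from the values, which ran from 4.08 to 14.2 and were not centred by gene. Because RMA equalises the probe distributions of the arrays, a change in total RNA per cell cannot be seen, and changes are relative to the bulk of genes, whose median log2 change was -0.02.

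Each probe set is named by an Entrez gene number, and GEO's platform annotation pairs 20239 of the 21225 probe sets with exactly 1 gene symbol and none with several. The remaining 986 (4.65%) are unnamed here and entered only an alternative. All 20239 Entrez numbers and symbols were found in RefSeq's gene table for GRCm38.p6. Since no build is named for the array, no coordinates are reported. Each gene had 1 probe set, so the planned choice among several probe sets of a gene, and its alternative of averaging them, did not arise.

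Groups were taken from the sample titles. The principal model, fixed before the data were examined together with the gene lists, the alternatives and the rule for named genes, was limma (version 3.58.1, R 4.3.3) with lmFit and eBayes on the deposited values of all 6 arrays, with the group as the only factor and no filter on dim genes. The test was two-sided, p-values were Benjamini-Hochberg adjusted over the 20239 genes, and genes with an adjusted p under 0.05 were called. A log2 change is PDGF-BB minus control, and standard errors and 95% intervals are those of the moderated fit. Folds are 2 to the power of the log2 change. Where the lower group's mean lay under 7.44, the 90th percentile of 22 lymphocyte, mast cell and erythroid markers, a level that takes those markers as absent and was chosen after the results were seen, the fold is given as "at least", since a value near background understates it, and no fold is given where both means lay under it. Arrays give no read depth, and their number, 3 per group, limits the precision; no detection calls were used, so dim genes may lie at background.

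The 33 gene lists (23 of pathways and gene families, 10 of cell type markers) were written from textbook knowledge, and 737 of their 786 genes were measured under a symbol or a synonym; the others are not analysed here. Lists overlap. A list's shift against all other genes was tested with camera at a preset correlation between genes of 0.01, adjusted over the 33 lists. Camera with an estimated correlation and fry were alternatives; fry's directional p tests whether the members move, on balance, 1 way, and its mixed p whether they change either way, and neither compares the list with other genes. With an estimated correlation none of the 10 list calls held. With 4 residual degrees of freedom that correlation is itself imprecise, and over these 10 lists it ranged from -0.03 (ERK) to 0.84 (mitosis). The ERK and FoxO lists lost their calls at estimates below the preset value (-0.03 and -0.02). A higher correlation between their genes was therefore not the reason. With an estimate, camera also judges its statistic on those 4 degrees of freedom, so a list's p can rise without any correlation.

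The genes named are, in each direction, the 12 with the largest change among called genes whose 3 PDGF-BB arrays lie beyond the 3 control arrays, leaving out gene-model names; Pdgfrb, Pdgfra, Pdgfb, Itga1, Itgb1, Rgs5, Cspg4, Acta2 and Des in every case; and of each list up to 4 members with the smallest p, up to 2 in each direction where called members went both ways. This gave 142 genes, not all of which are described.

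The labels number the arrays 1 to 3 in both groups without saying what a number shares. Deviations from the group means correlated at 0.25, 0.32 and 0.25 across genes between the control and PDGF-BB arrays numbered 1, 2 and 3, and at -0.28 to 0.01 between differently numbered arrays of the 2 groups, so the numbers were taken to pair the arrays. The principal model stayed without the pairing, and the fit with the replicate number as a block is given wherever it changes a call or moves a count by over 1.5 times. No array was a copy of another: the median absolute difference between arrays of a group was 0.0896 to 0.105 log2 units. No scan date or slide was used, so batches other than the replicate number were not tested.

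Alternatives were a repeated quantile normalization, centring each array on its median, leaving out genes whose mean lay under the 25th or 50th percentile, eBayes with a trend and robust estimation, array weights, the replicate block, leaving out each array in turn, all 21225 probe sets, an adjusted p under 0.01, a fold of at least 1.5, and limma's treat against a fold of 1.2. The principal model was tested on simulated data with the real means and moderated variances of the 20239 genes and 200 genes changed by known amounts. For PDGF-BB against control it recovered 67.2% of 67 genes changed by 0.5 log2 units, 98.5% of 67 changed by 1 and 66 of 66 changed by 2, and called 9 of 20039 unchanged genes. The simulated values were drawn independently, without pairing of arrays or correlation between genes, so these rates do not cover either. Only 200 of the 20239 genes were changed, against 21.5% called in the data, so the adjusted threshold was stricter than the real one. The moderated variances are also already drawn towards a common value. The rates are therefore not those of the real test.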

Results

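Gene expression was measured on 1-colour arrays in total RNA from isolated mouse pericytes, the mural cells that wrap capillaries and small vessels, of the C57BL/6 background. The cells had been kept for 5 days with platelet-derived growth factor BB (PDGF-BB) at 100 ng/ml or without it. PDGF-BB is a homodimer of the PDGF B chain and the main ligand of PDGFR-β, the receptor tyrosine kinase by which endothelial cells recruit pericytes. There were 3 control arrays and 3 PDGF-BB arrays, numbered 1 to 3 in each group by the labels, and 20239 named genes with 1 probe set each were tested. The median log2 value of these genes lay between 8.43 and 8.46 on all 6 arrays. Arrays of the same group correlated across genes at r = 0.994 to 0.996, and arrays of different groups at r = 0.973 to 0.986. The labels do not say whether the arrays came from separate isolations or cultures, so the p-values measure the spread between these 6 samples, which may be technical.

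The single comparison of the design asks how the transcriptome of pericytes under sustained PDGF-BB differs from that of pericytes without it. PDGF-BB changed 4342 of 20239 genes (21.5%) in limma's moderated test with Benjamini-Hochberg adjustment, of which 2037 rose and 2305 fell. At least 2-fold changes were seen in 413 of the genes that rose and 254 of those that fell. Of the 33 lists, 6 shifted upwards in camera with a preset correlation, those of DNA replication, mitosis, the interferon response, cholesterol and fatty acid synthesis, the amino acid response and ERK pathway outputs. The other 4 that passed shifted downwards, those of the contractile apparatus, transforming growth factor beta (TGF-β) signalling, FoxO transcription factor targets and the Wnt pathway. None of the 10 calls held with an estimated correlation (adjusted p = 0.14 to 0.49 with an estimated correlation). In all 4342 genes the 3 PDGF-BB arrays lay on 1 side of the 3 control arrays, which adds no support, since passing the test favours such genes. Such a separation occurred in 37.6% of all genes, against 10% given by chance for 3 arrays against 3. The genes share the same 6 arrays, so they are not independent draws. Without PDGF-BB array 1 or 2 the count of genes that fell was 1516 or 1514, and the total was 2947 or 2934.

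**Figure D1:**
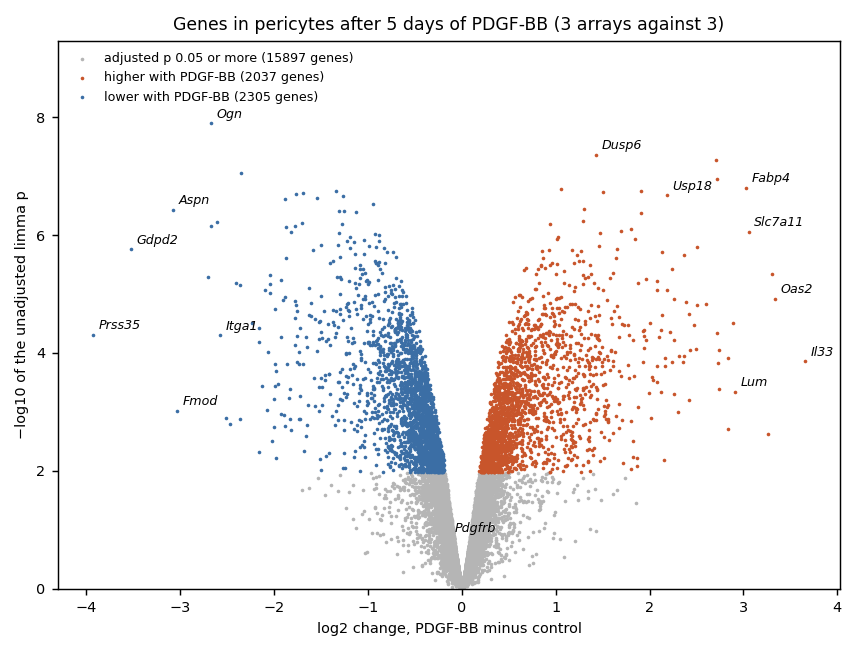
Log2 change (PDGF-BB minus control, horizontal axis) against −log10 of the unadjusted limma p (vertical axis) for each of 20239 genes, coloured by whether the adjusted p was under 0.05. The 2037 genes that rose include Il33, Oas2, Slc7a11 and Fabp4, the 2305 that fell include Prss35, Gdpd2, Aspn, Ogn and Itga1, and Pdgfrb lies near 0.

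Il33, an alarmin cytokine of the interleukin 1 family (Entrez gene 77125), rose at least 12.6-fold, from a log2 value of 7.33 ± 0.51 to 10.98 ± 0.99 (SD, n = 3 each, adjusted p = 0.0033, limma). Oas2, an interferon-induced 2′-5′-oligoadenylate synthetase, rose 10.1-fold (log2 change 3.34, SE 0.31), and Irf7, a transcription factor of the interferon system, 7.41-fold (2.89, SE 0.31). Slc7a11, the cystine/glutamate exchanger, rose at least 8.32-fold (3.06, SE 0.19) and Fabp4, a fatty acid binding protein of adipocytes, 8.14-fold (3.02, SE 0.15). Lum, the small leucine-rich proteoglycan lumican, rose 7.53-fold (2.91, SE 0.47), and Akr1c18, an aldo-keto reductase that inactivates progesterone, at least 7.15-fold (2.84, SE 0.37). The other increases among the 12 largest were those of Ifi208, Ifi213, Ranbp3l, AI504432 and AI593442, with log2 changes between 2.74 and 3.31. Except for Ranbp3l, their control means lay under 7.44, so these changes are lower bounds. Ifi213 had an adjusted p of 0.052 without PDGF-BB array 1, and Ranbp3l one of 0.053 without PDGF-BB array 1 and 0.054 without PDGF-BB array 2. Ifi208, Ifi213, Oas2 and Akr1c18 have close relatives in the mouse genome, and their probes were not checked for shared sequence.

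Prss35, a secreted serine protease-like protein (Entrez gene 244954), was at least 15.2-fold lower (log2 change -3.93, SE 0.45, n = 3 each, adjusted p = 0.0022, limma). Gdpd2, a glycerophosphodiester phosphodiesterase, was 11.5-fold lower (log2 change -3.52, SE 0.24). Aspn, Fmod and Ogn, the small leucine-rich proteoglycans asporin, fibromodulin and osteoglycin, were 8.42-fold, 8.17-fold and 6.36-fold lower. Ogn had the smallest p of all genes (13.31 ± 0.06 against 10.64 ± 0.16, adjusted p = 2.6e-04, limma). P4ha3, a prolyl 4-hydroxylase subunit used in collagen maturation, was 6.40-fold lower, and Mfap5, a microfibril-associated glycoprotein, 5.72-fold lower. Itga1, the α1 integrin subunit (Entrez gene 109700), which pairs with β1 to bind collagen and laminin, was 5.96-fold lower (10.73 ± 0.33 against 8.15 ± 0.58, log2 change -2.58, 95% interval -3.27 to -1.88). The remaining 4 of the 12 were Prss23, Slc10a6, Mest and Lims2, with log2 changes between -2.71 and -2.41. Mest had an adjusted p of 0.051 without PDGF-BB array 1.

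**Figure D2:**
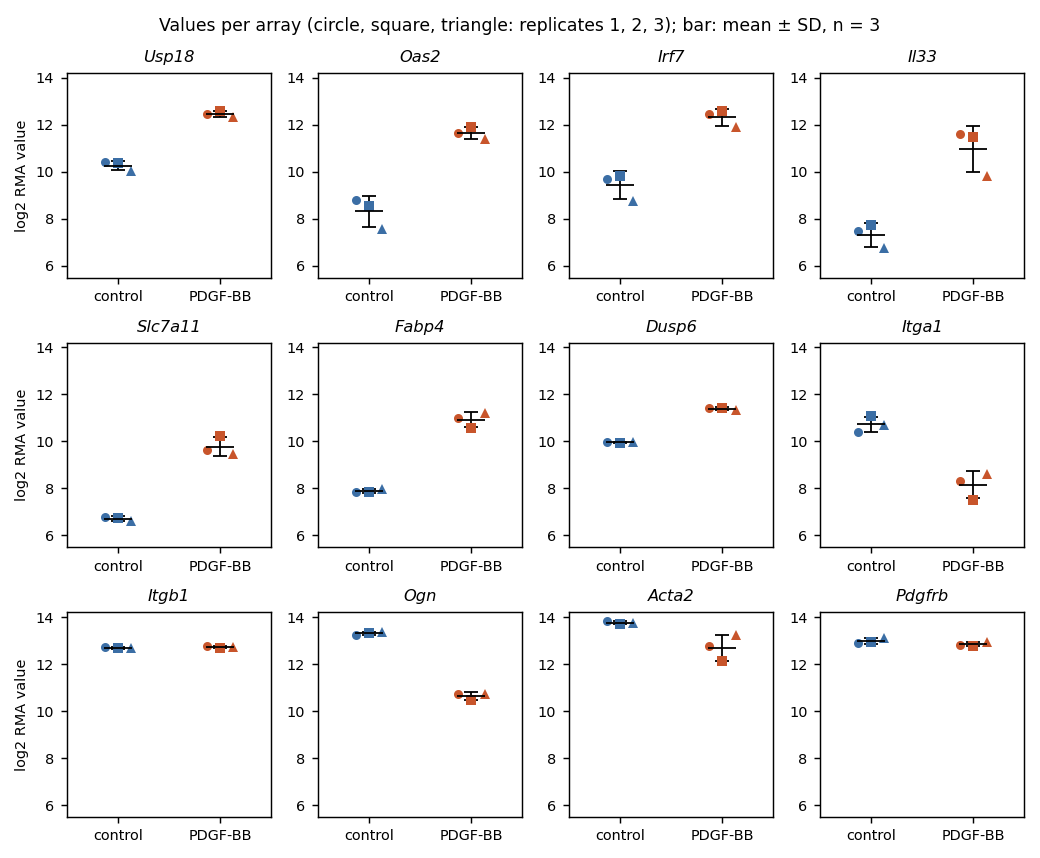
Log2 RMA value (vertical axis) of 12 genes on each of the 6 arrays, with symbols for the replicate number and a bar for the mean ± SD of each group (n = 3). Itga1 lies lower on all 3 PDGF-BB arrays while Itgb1 and Pdgfrb overlap between the groups, and within both groups array 3 has the lowest Oas2, Irf7 and Il33.

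In the list of S phase and DNA replication genes, all 34 measured members rose, with a median log2 change of 1.22 (camera adjusted p = 4.2e-23, and adjusted p = 0.37 with an estimated correlation). They include Cdc6, which loads the replicative helicase (2.29-fold), Ccne1, the G1/S cyclin E1 (2.31-fold), Tyms, thymidylate synthase (2.13-fold), and E2f1, the transcription factor of S phase entry (1.48-fold). Of the 36 mitosis genes 30 rose and none fell, with a median log2 change of 1.02 (camera adjusted p = 3.3e-15, and adjusted p = 0.49 with an estimated correlation). Cdk1, the mitotic cyclin-dependent kinase, rose 1.91-fold, and Nuf2 and Ndc80, kinetochore proteins, 2.89-fold and 2.15-fold. Adjusted over the list alone, 34 of 34 and 36 of 36 rose. The median difference of the mitosis list was 0.50, 0.88 and 1.72 log2 units between the arrays numbered 1, 2 and 3. The number of mitosis genes that rose was 19 without control array 2, and 10, 9 and 7 without PDGF-BB array 1, 2 and 3. Of 23 p53 targets and cell cycle inhibitors, 3 rose and 5 fell, among them Sesn2 and Eda2r (1.62-fold and 1.53-fold higher) and Fas and Btg2 (2.27-fold and 1.55-fold lower), and that list did not shift as a whole (adjusted p = 0.23). The counts were also 3 and 5 adjusted over the list alone, and without control array 1, 2 of these genes rose and 8 fell.

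Interferon response genes made up the list with the largest median change. Of 31 measured members 28 rose and none fell, with a median log2 change of 1.59 (camera adjusted p = 8.2e-23, and adjusted p = 0.37 with an estimated correlation); adjusted over the list alone 29 rose. Usp18, the protease that removes ISG15 from proteins, rose 4.55-fold (10.27 ± 0.19 to 12.46 ± 0.12, n = 3 each), Oasl1 3.77-fold, Psmb8, an immunoproteasome subunit, 3.23-fold, and Stat2, part of the type I interferon transcription complex, 2.41-fold. Oasl1 and the list's other Oas and Ifit members have close relatives too, and their probes were not checked for shared sequence either. The median difference of the list was 1.58, 1.65 and 1.65 log2 units in the pairs of arrays numbered 1, 2 and 3. Chemokine, cytokine and inflammation genes went both ways, with 9 of 32 higher and 5 lower, and did not shift as a list (adjusted p = 0.10; 10 higher and 5 lower adjusted over the list alone). Ccl8 and Ccl2, monocyte-attracting chemokines, rose at least 6.07-fold and 1.67-fold, whereas Vcam1, the adhesion molecule, and Tnfaip3, an inhibitor of NF-κB signalling, were 1.84-fold and 1.76-fold lower. Without PDGF-BB array 2 or 3 that list's median was 0.18 or 0.24 and its adjusted p 0.026 or 0.040, and 3 rather than 5 of its genes fell without control array 2 or PDGF-BB array 3. Among markers of immune cells, 2 of 21 macrophage markers rose (Mpeg1, at least 2.64-fold, and Cd14, 1.74-fold), 2 fell (Lyz2, log2 change -0.49, and Cd68, 1.34-fold), and the counts adjusted over the list alone were the same. The Cd68 call was lost without PDGF-BB array 1 (adjusted p = 0.067) or 2 (0.058), and without PDGF-BB array 2 the counts were 3 and 1. None of 16 lymphocyte and mast cell markers passed in limma, and 0 had an unadjusted p under 0.05. These markers were among those taken as absent to set the background level.

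Of 26 measured genes of cholesterol and fatty acid synthesis 24 rose and none fell (median log2 change 0.69, camera adjusted p = 3.3e-19, and adjusted p = 0.25 with an estimated correlation); adjusted over the list alone the count was also 24. Cyp51 and Msmo1, which remove methyl groups from the sterol ring, rose 2.26-fold and 2.08-fold, Fdps, farnesyl diphosphate synthase, 1.60-fold, and Elovl6, a fatty acid elongase, 2.01-fold. In the list of amino acid response and unfolded protein response genes 19 of 28 rose and none fell (median 0.59, camera adjusted p = 9.4e-13, and adjusted p = 0.28 with an estimated correlation; 23 rose adjusted over the list alone). Besides Slc7a11, these included Chac1, which degrades glutathione (2.44-fold), Psph, the last enzyme of serine synthesis (1.72-fold), and Sesn2, a leucine sensor (1.62-fold). Glycolysis and hypoxia genes did not shift as a list (adjusted p = 0.23): 3 of 29 rose, among them Slc2a1, the glucose transporter GLUT1 (1.37-fold), and 4 fell, among them Pfkfb3, a glycolytic regulator (2.25-fold lower), and Ndrg1 (1.94-fold lower). Adjusted over the list alone 6 rose and 5 fell. With the replicate number as a block 8 glycolysis and hypoxia genes rose, with each array centred on its median 5 rose, and without genes under the 50th percentile of mean signal 5 rose and 5 fell. Leaving out 1 array, the count that rose ranged from 1 (without control array 3 or PDGF-BB array 1) to 5 (without control array 1 or PDGF-BB array 2), and 2 fell without control array 3 or PDGF-BB array 2. Without PDGF-BB array 2 the list's adjusted p was 0.025 (median 0.17).

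ERK is activated by PDGFR signalling, and FoxO factors are repressed by AKT signalling. In the list of ERK pathway outputs 14 of 30 genes rose and 3 fell (median log2 change 0.35, camera adjusted p = 8.5e-05, and adjusted p = 0.14 with an estimated correlation). Adjusted over the list alone 16 rose and 7 fell. Dusp6, the ERK phosphatase, rose 2.69-fold (9.96 ± 0.03 to 11.39 ± 0.06, n = 3 each) and Etv5, an ETS transcription factor, 2.83-fold. The 3 members that fell were Fos (2.28-fold lower), Dusp1 (1.70-fold lower) and Fosb (log2 change -1.51, named after its value was seen), and with the replicate number as a block 6 rather than 3 fell. Of 22 FoxO targets 14 fell and 1 rose (median -0.50, camera adjusted p = 8.0e-06, and adjusted p = 0.14 with an estimated correlation; 15 fell and 2 rose adjusted over the list alone). Pdk4, pyruvate dehydrogenase kinase 4, and Pik3ip1, an inhibitor of PI3K, were 2.99-fold and 2.65-fold lower, while Trib2, a pseudokinase, was 1.72-fold higher. With the replicate number as a block, and without control array 1 or PDGF-BB array 2, 2 FoxO targets rose.

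The PDGF receptors themselves did not pass the test. Pdgfrb (Entrez gene 18596) measured 12.98 ± 0.11 in control and 12.85 ± 0.09 with PDGF-BB (SD, n = 3 each), a log2 change of -0.14 with a 95% interval of -0.32 to 0.05 (adjusted p = 0.31, limma). Pdgfra had a log2 change of -0.07 (95% interval -0.25 to 0.10, adjusted p = 0.59) and Pdgfb one of -0.14 (-0.38 to 0.11, adjusted p = 0.44). Of the 6 PDGF ligand and receptor genes, Pdgfa and Pdgfd were 1.42-fold and 2.17-fold lower, also adjusted over the list alone, and the list did not shift as a whole (adjusted p = 0.13). Pericyte markers did not shift either (median -0.06, adjusted p = 0.70): of 19 measured, Anpep, aminopeptidase N, rose 1.83-fold and Cd248, endosialin, was 1.26-fold lower. Cd248 had an adjusted p of 0.081 to 0.13 without control array 2 or 3 or any 1 of the PDGF-BB arrays. Cspg4, the NG2 proteoglycan, had a log2 change of 0.91 (95% interval 0.23 to 1.58, adjusted p = 0.065), which passed with the replicate number as a block (adjusted p = 0.015) and without PDGF-BB array 3 (0.021). Rgs5 and Des, further mural cell genes, had log2 changes of -0.06 (adjusted p = 0.59) and 0.08 (adjusted p = 0.58). Both group means of Des (7.24 and 7.32) and the PDGF-BB mean of Pdgfb (7.43) lay under the background level of 7.44. The means of Rgs5 (7.77 in control and 7.71 with PDGF-BB) lay only a little above it. A change in such dim genes may go unseen, so the absence of a call says little there. Of the 19 pericyte markers 12 lay above 7.44, and the same limit holds for the rest. Adjusted over the list alone 1 pericyte marker rose and 0 fell, with the block 2 rose and 3 fell, without PDGF-BB array 3, 2 rose, and without control array 2 or 3 or PDGF-BB array 2, 0 fell.

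Of 23 contractile smooth muscle genes 12 fell and 1 rose (median log2 change -0.50, camera adjusted p = 4.7e-05, and adjusted p = 0.36 with an estimated correlation; 15 fell and 1 rose adjusted over the list alone). Acta2, smooth muscle α-actin, was 2.10-fold lower (13.76 ± 0.06 against 12.69 ± 0.56, n = 3 each, adjusted p = 0.024, limma), with an adjusted p of 0.058 to 0.067 when any 1 control array or PDGF-BB array 1 was left out. Lmod1, which nucleates smooth muscle actin filaments, was 2.01-fold lower and Vcl, vinculin of focal adhesions, 1.55-fold lower. Smtn, smoothelin, was 1.26-fold higher (adjusted p = 0.044), a call that was lost with the replicate number as a block (0.067), without control array 2 (0.13) or 3 (0.13), and without PDGF-BB array 1 (0.066), 2 (0.13) or 3 (0.095). In the TGF-β list 15 of 27 genes fell and 3 rose (median -0.47, camera adjusted p = 0.0014, and adjusted p = 0.47 with an estimated correlation; 15 fell and 3 rose adjusted over the list alone). The ligands Tgfb2 and Tgfb3 were 2.69-fold and 1.80-fold lower, while Tgfb1 and its receptor Tgfbr1 were 1.48-fold and 1.32-fold higher and Bmp2, named after its value was seen, had a log2 change of 1.87. The Tgfbr1 call was lost without control array 1 or 2 or PDGF-BB array 1 or 3 (adjusted p = 0.059 to 0.084). Without control array 1 or 2 or PDGF-BB array 1, 1 rather than 3 of the genes of that list rose. Of 27 Wnt pathway genes 8 fell and 1 rose (median -0.19, camera adjusted p = 0.012, and adjusted p = 0.37 with an estimated correlation; 9 fell and 1 rose adjusted over the list alone). Ccn5, a secreted matricellular protein, was 3.39-fold lower and Fzd2, a Wnt receptor, 1.55-fold lower, while Ccn4, a relative of Ccn5, was 1.88-fold higher.

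**Figure D3:**
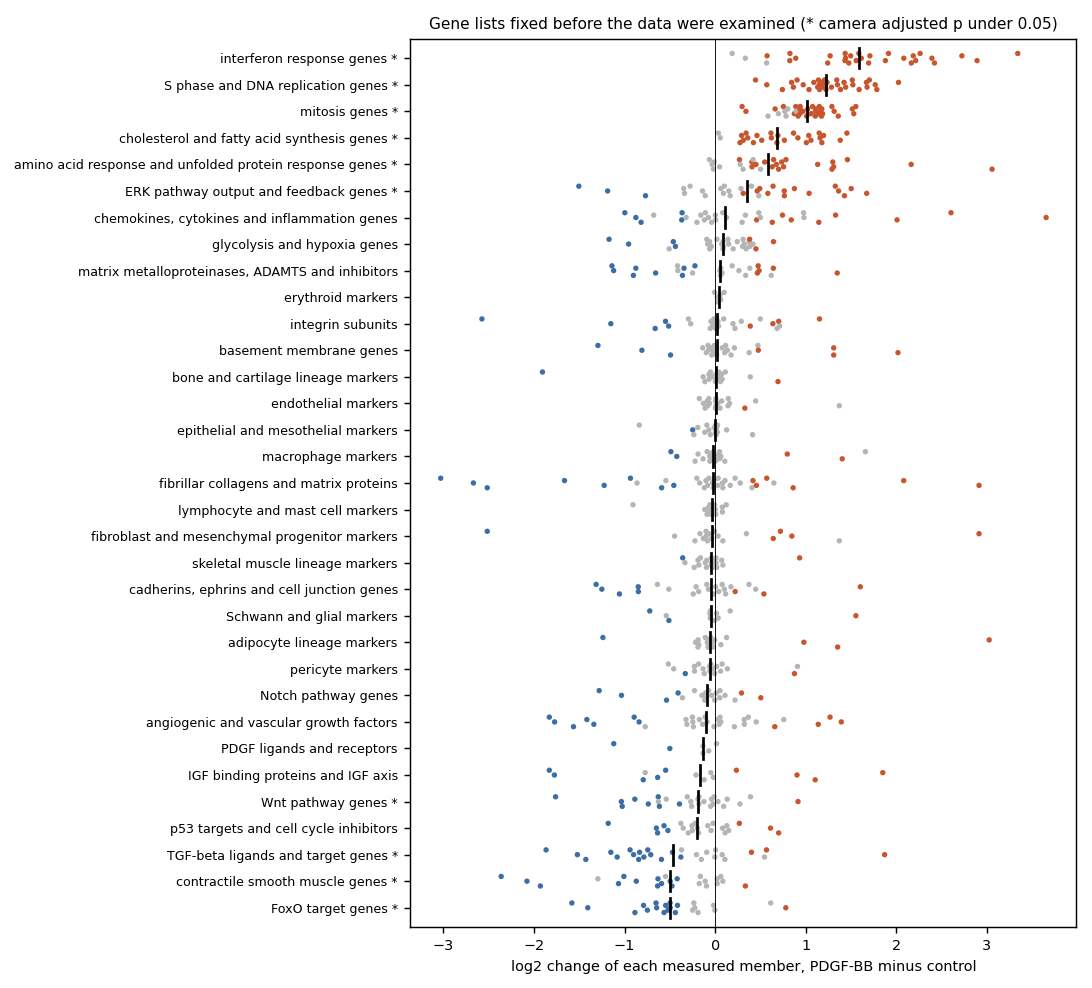
Log2 change (PDGF-BB minus control, horizontal axis) of each measured member of the 33 gene lists, with the list median as a black line, orange points for members that rose, blue for members that fell and grey for those with an adjusted p of 0.05 or more. The 6 starred lists at the top lie mainly to the right of 0 and the other 4 starred lists mainly to the left.

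Integrin, adhesion and matrix genes changed in both directions, and none of these lists shifted as a whole (adjusted p = 0.23 to 0.91). Of 26 integrin subunits 4 rose and 5 fell (4 and 6 adjusted over the list alone). Itga1 had the largest change, whereas its partner Itgb1 (Entrez gene 16412) measured 12.69 ± 0.04 and 12.73 ± 0.03 (log2 change 0.04, 95% interval -0.09 to 0.17, adjusted p = 0.72, limma). Itgb3, the β3 subunit of vitronectin receptors, and Itgb2, the leukocyte β2 subunit, rose 1.63-fold and 1.31-fold, and Itgb5 was 1.43-fold lower. The Itgb5 call was lost without PDGF-BB array 2 (adjusted p = 0.057), PDGF-BB array 3 (0.056) or control array 3 (0.061). Among 24 cadherin, ephrin and junction genes 3 rose (4 adjusted over the list alone), including Gja1, a gap junction connexin (3.03-fold), and 5 fell (6 adjusted over the list alone), including Cdh11, a mesenchymal cadherin (2.49-fold lower), and Efnb1, ephrin B1 (1.80-fold lower). Of 25 basement membrane genes 4 rose, including Col18a1 and Agrn (2.48-fold each), and 3 fell, including Nid2, a nidogen (2.45-fold lower), with the same counts adjusted over the list alone. Of 35 fibrillar collagens and matrix proteins 6 rose and 8 fell (7 and 8 adjusted over the list alone), with Col6a3 4.23-fold higher and Lox, the collagen cross-linking enzyme, 2.34-fold lower. Of 25 metalloproteinases and inhibitors 5 rose, including Mmp10, a stromelysin (2.54-fold), and 8 fell, including Timp3, an inhibitor of metalloproteinases (2.20-fold lower), and adjusted over the list alone 7 rose and 10 fell. Leaving out 1 array at a time gave 2 integrin subunits that rose without control array 2 or PDGF-BB array 1, and fewer that fell without PDGF-BB array 2 (1), control array 3 (2), control array 2 (3) or PDGF-BB array 3 (3). It gave 1 junction gene that rose without control array 3 or PDGF-BB array 1. Without control array 2 or 3 or PDGF-BB array 1 or 2, 1 basement membrane gene fell and 3 to 5 metalloproteinase genes fell. The count of matrix proteins that rose was 3 without control array 1 or 3 or PDGF-BB array 2, and 2 without PDGF-BB array 3.

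Growth factor and Notch genes also went both ways without a list shift (adjusted p = 0.24 to 0.61). Of 32 angiogenic and vascular growth factor genes 4 rose and 7 fell, also adjusted over the list alone. Hgf, hepatocyte growth factor, and Ereg, the EGF receptor ligand epiregulin, rose 2.20-fold and 2.41-fold, and Vegfd, a lymphangiogenic growth factor, and Nrg1, neuregulin 1, were 3.42-fold and 2.96-fold lower. Of 14 genes of the insulin-like growth factor axis 4 rose and 5 fell (4 and 6 adjusted over the list alone). Stc1 and Stc2, the stanniocalcins, rose 3.60-fold and 2.15-fold, while Pappa, the protease that stanniocalcins inhibit, was 3.42-fold lower and Igf2 3.56-fold lower. Of 20 Notch pathway genes 2 rose and 4 fell (3 and 5 adjusted over the list alone). Jag1, a Notch ligand, was 2.43-fold lower and Maml2, a Notch coactivator, 2.05-fold lower, while Notch1 and Dll1 were 1.42-fold and 1.22-fold higher. Leaving out 1 array gave 2 growth factor genes that rose without control array 2 or 3 or PDGF-BB array 1 or 3. It gave 2 insulin-like growth factor genes that rose without any 1 control array or PDGF-BB array 3. No Notch gene rose without control array 2 or any 1 PDGF-BB array (adjusted p of Notch1 0.061 to 0.12, of Dll1 0.073 to 0.11), and 1 rose without control array 1 (Dll1 0.087) and with the replicate number as a block (Dll1 0.053).

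Markers of other cell types that such cultures can hold did not shift as lists, with adjusted p between 0.56 and 0.91 for the 10 lists. Many are dim: only 5 of 20 endothelial, 3 of 21 macrophage, 4 of 21 skeletal muscle and 3 of 18 bone and cartilage markers reached the 50th percentile of mean signal. For the adipocyte, Schwann and fibroblast lists 8 of 19, 5 of 12 and 14 of 19 did. The epithelial, lymphocyte and erythroid lists kept fewer than the 3 members that a list test needs. A change in dim markers may go unseen, so the absence of a shift says little there. None of 6 erythroid markers passed in limma, and 0 had an unadjusted p under 0.05. Single markers did change: besides Fabp4, Lpl, lipoprotein lipase, rose 2.55-fold in the adipocyte list (3 of 19 rose, 1 fell, also adjusted over the list alone), and Pdpn, podoplanin, rose 1.56-fold in the fibroblast list beside Lum (4 of 19 rose, 2 without control array 3, and Mfap5 fell, with the same counts adjusted over the list alone). The gene that fell in the adipocyte list, Aoc3, was lost without control array 2 or any 1 PDGF-BB array (adjusted p = 0.058 to 0.12). Gap43, a growth cone protein, rose 2.93-fold and Pmp22, a myelin protein, was 1.65-fold lower among 12 Schwann and glial markers, where 1 rose and 2 fell (1 and 3 adjusted over the list alone), the other being Mbp, whose call was lost without control array 1 or 2 or PDGF-BB array 2 or 3 (adjusted p = 0.057 to 0.072). Sox9, a chondrocyte transcription factor, rose 1.62-fold and Omd, osteomodulin, was at least 3.75-fold lower among 18 bone and cartilage markers, the only ones that passed, also adjusted over the list alone. Of 20 endothelial markers 1 passed, Plvap (1.25-fold higher), whose call was lost without control array 2 or 3 or any 1 PDGF-BB array (adjusted p = 0.087 to 0.11), while Cdh5 passed without PDGF-BB array 3 (0.0053). Cd34, which is on the endothelial and fibroblast lists, had a log2 change of 1.37 with a 95% interval of -0.32 to 3.06 (adjusted p = 0.25). It passed with the replicate number as a block (0.0049) and without control array 2 (0.036), where its log2 change was 2.15. Of 18 epithelial and mesothelial markers only Krt7 passed (log2 change -0.25, adjusted p = 0.047, and 0.052 with the block), and it passed without control array 2 but not without any other array (0.081 to 0.14). In the skeletal muscle list Acta1 was 1.28-fold lower and Chrna1 at least 1.91-fold higher, and the latter call was lost without PDGF-BB array 1 or any 1 control array (0.061 to 0.11), and 2 fell with the block or without PDGF-BB array 2. Adjusted over the list alone 0 endothelial and 0 epithelial markers passed, and of the skeletal muscle markers 1 fell. The median was below 0, and the mean and the camera direction above it, for the adipocyte, fibroblast and macrophage lists (means 0.16, 0.16 and 0.11). The mean was below 0 (-0.02, -0.05 and -0.05), and the median and the camera direction above it, for the integrin, metalloproteinase, and bone and cartilage lists.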

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

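All alternatives here were planned. No gene of the naming rule that passed, and no list that was called, reversed its direction under any of them. The count of 4342 genes fell to 2037 (968 higher, 1069 lower) at an adjusted p under 0.01, to 1662 (897 higher, 765 lower) with a fold of at least 1.5, and to 1256 (653 higher, 603 lower) with treat against a fold of 1.2, by construction stricter criteria. Leaving out 1 array gave 2934 to 4219 genes (1420 to 2031 higher, 1514 to 2188 lower), with fewer arrays fitted, and 10 to 12 lists. With the replicate number as a block 4741 genes were called, 4005 of them shared with the unblocked model and all 4005 in the same direction. The pairing changed the calls of Cspg4, Cd34, Smtn, Krt7 and Dll1, and no other call among the 142 genes of the naming rule or the 33 lists. The other scalings, filters, moderation, array weights and the use of all probe sets kept the gene counts within 1.5 times, between 3913 and 4529, and those run on lists kept the list count at 10. Among single genes they lost Smtn (adjusted p = 0.059), Notch1 (0.055), Aoc3 (0.054) and Krt7 (0.085) with quantile normalization repeated, Krt7 with median centring (0.068), and Aoc3 (0.078), Chrna1 (0.054) and Krt7 (0.060) with trend and robust estimation, and gained Cspg4 with the 50th percentile filter (0.042) and array weights (0.049). Within lists, without the genes under the 50th percentile 2 rather than 4 growth factor genes rose (25 of 32 tested), 2 rather than 4 integrin subunits (11 of 26 tested) and 2 rather than 1 FoxO targets, the last also without those under the 25th percentile. Both filters left out Omd, and macrophage markers then had 2 higher and 1 lower with the 25th percentile and 1 and 1 with the 50th. With an estimated correlation 0 of 33 lists passed in camera (4 at an unadjusted p under 0.05), against 10 with the preset value and 13 with fry, which shared 9 of the 10, lost the mitosis list (adjusted p = 0.057) and added PDGF ligands and receptors, junctions, Notch and Schwann markers (0.011 to 0.039). By fry's mixed p 30 of the 33 lists changed. Of the 121 genes of the naming rule that passed, 19 lost their call in at least 1 leave-out, 3 of them among the 24 largest changes. Averaging a gene's probe sets could not give a value, since each gene has 1. Without the genes under the 25th and 50th percentile of mean signal 4370 and 3913 were called; detection calls were not used here, so which dim genes lay at background is unknown.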

Other observations

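The tests of the protein synthesis, proteasome, lysosome and antigen presentation lists, of the neighbouring genes, of immune cell RNA and of the mural cell share, and the background levels used for interferon genes, immune cell genes and pericyte markers and the lower quartile used for imprinted genes, were chosen only after results were seen. Of 28 ribosome biogenesis genes 23 rose and none fell (median log2 change 0.52, camera adjusted p = 1.4e-14 over 11 lists, and adjusted p = 0.16 with an estimated correlation), with Nop56, a box C/D ribonucleoprotein, 0.81 (SE 0.08) higher and Dkc1, dyskerin, 1.13 (SE 0.24) higher on the log2 scale. Of 19 cytosolic aminoacyl-tRNA synthetases 15 rose and none fell (median 0.57, adjusted p = 1.2e-11, and adjusted p = 0.16 with an estimated correlation), among them Aars, alanyl-tRNA synthetase (1.01, SE 0.08). Of 30 proteasome subunits 13 rose and none fell (median 0.28, adjusted p = 4.9e-10, and adjusted p = 0.23 with an estimated correlation). Of 12 antigen presentation genes 10 rose (median 0.68, adjusted p = 7.9e-08, and adjusted p = 0.16 with an estimated correlation), among them H2-K1, a class I histocompatibility molecule with close relatives (1.31, SE 0.15), while B2m, its light chain, had a log2 change of 0.02 (SE 0.05, adjusted p = 0.86). B2m measured 13.32 in control and 13.34 with PDGF-BB, near the highest values of the arrays, where a rise may be understated. Lysosome genes, with 2 of 29 higher and 4 lower, did not shift (camera adjusted p = 0.42). The genes named here were chosen after their values were seen.

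The proteoglycan genes Aspn, Omd and Ogn are neighbours on chromosome 13, in that order after Ecm2 in the GRCm38.p6 annotation, and all 4 fell. Genes that overlap this stretch are not described here. Their log2 changes were -0.94 (SE 0.20) for Ecm2, -3.07 (SE 0.17) for Aspn, -1.91 (SE 0.18) for Omd and -2.67 (SE 0.09) for Ogn. The PDGF-BB mean of Omd (5.79) lay under 7.44, so its fall may be understated.

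Of 31 interferon response genes 28 rose (median 1.59, camera adjusted p = 0.37 with an estimated correlation), and the labels name no added interferon. The rise was not in 1 array pair alone, since the lowest of the 3 pairs' lower quartiles over the list was 1.09. With 28 of 31 members called this was likely beforehand, because passing the test favours genes that differ in all pairs. It therefore adds no support. RNA from immune cells stays open: over 20 genes of blood-derived cells, 8 of them also in a fixed list, the upper quartile of the log2 changes was 0.047, but 14 of the 20 lay under 7.44, the 90th percentile of 22 lymphocyte, mast cell and erythroid markers, where a transcript may go unseen (a level that takes immune markers as absent and so assumes part of what is tested, but 15 lay under 7.70, that of the 6 erythroid markers alone). Of the 6 genes above 7.44 Arhgdib (0.44) and Itgb2 (0.39) rose and Cd53 had 1.66 (SE 0.56, adjusted p = 0.082, and 0.00026 with the replicate number as a block), while Rac2, Hcls1 and Ptpn6 had -0.16, -0.08 and -0.04. Higher transcripts of the interferon genes themselves stay open too: none of 15 passed in limma (0 at an unadjusted p under 0.05) and the highest upper 95% limit was 0.28, within the bound of 0.3 set before against this explanation, but that bound was wrong for these genes, since 10 of the 15 lay under 7.44. Without these levels, chosen after these values were seen, both tests would have argued against their explanations.

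Of the contractile and TGF-β lists 12 of 23 and 15 of 27 genes fell while 1 and 3 rose (medians -0.50 and -0.47, adjusted p = 0.36 and 0.47 with an estimated correlation). For the pericyte markers above 7.44, the values argue against a smaller share of mural cells as the whole cause. This holds only if PDGF-BB left the level of these markers per mural cell unchanged, which was not measured. A rise per cell could offset a loss of cells. The lower quartile of these 12 markers was -0.25 (-0.21 over all 19) and their median -0.16, short of the contractile list's median of -0.50. Pdgfrb was at -0.14 (95% interval -0.32 to 0.05) and Cspg4 at 0.91 (0.23 to 1.58, limma adjusted p = 0.065), and the pericyte list did not shift (camera adjusted p = 0.70). No list of other cell types rose, but only 5 of 20 endothelial and 3 of 21 macrophage markers reached the 50th percentile of mean signal, against 14 of 19 fibroblast markers. Replacement by cells that carry the same markers would not be seen. A candidate explanation is lower expression of targets of the YAP and TEAD transcription regulators: leaving out the 5 targets whose values had been seen, 14 of 19 fell and 1 rose (median -0.49, camera p = 1.3e-05, and p = 0.061 with an estimated correlation), among them Crim1 (-1.51, SE 0.16), Nt5e (-1.10, SE 0.10) and Ajuba (-1.15, SE 0.18), while Fjx1 rose (0.74, SE 0.08) and Axl and Ankrd1 had 0.06 and -0.07. Of the 24 measured targets 3 are also in the contractile or TGF-β lists, and YAP activity itself was not measured. The fall of these targets occurred beside that of the 2 lists and does not show its cause. A smaller share as part of the cause cannot be told apart from a change within the cells, since the lowest lower 95% limit among Pdgfrb, Cspg4 and Mcam was -1.02, that of Mcam (-0.52, adjusted p = 0.15, and 0.023 with the replicate number as a block), beyond the contractile list's median.

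Mest and Plagl1, both imprinted, fell (-2.47 and -2.16, SE 0.50 and 0.26), as did Igf2, also imprinted (-1.83), while Igf2r, imprinted too, rose (0.23, adjusted p = 0.026). Whether a wider imprinted growth network may be lower stays open: the 18 members not seen before the test had a median of -0.069 (camera p = 0.37, and p = 0.40 with an estimated correlation) with a lower quartile of -0.21. A median above -0.1 with a camera p of 0.05 or more, set before as the bound against this explanation, was met, so the planned test argued against it, but not by more than the members' spread, a criterion applied after the result was seen. None of the 18 passed in limma, 2 had an unadjusted p under 0.05, and 3 passed with the replicate number as a block, Grb10 (-0.52), Nnat (-0.93) and Ndn (-0.52). The full list of 24 had an adjusted p of 0.16, and 0.024 with the block.

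For 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 4342 genes (1 of 10 splits with as many, the real one included) and the highest other gave 0, both among the 3 other splits that part all 3 numbered pairs and among the 6 that part 1. For the lists the real split gave 10 and the highest other 11, and 3 of the 10 splits gave at least 10. Every other split places 2 arrays of 1 group with 1 of the other on each side, so part of the difference between the groups remains in it. The difference also enters the spread within each side, so a count of 0 genes was likely there. The part that remains is alike in all of them, yet they gave 3 to 11 lists, so it alone does not set the count. A list count as large as the real one also arose from splits that mix the 2 groups. These splits are not free of the PDGF-BB effect. Neither their gene counts nor their list counts show what would arise without it.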
